A study of Mus musculus with 4 samples.

How the data were processed

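RNA-seq was run on sorted recruited alveolar macrophages from WT and homozygous R213G male mice 7 days after bleomycin, with 2 libraries per genotype. Per the labels' protocols, RNA was isolated from the sorted cells and directional poly(A) libraries were made. The authors deposited raw counts per gene symbol, 1 column per library, with no normalization. Per the submitters' processing notes, the tools were STAR 2.5.1b and featureCounts from Subread 1.4.4, with the genome build GRCm38. The annotation release, the strand setting, the treatment of reads that map to several places and any filter on genes are not given in the sources used here. Reads of genes with near-identical copies (such as Bcl2a1d, Ear2, Hspa1a, H2-DMb2 and the ribosomal protein genes) and of overlapping or antisense genes could therefore be split or lost in ways that the counts do not show.

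The table held 16360 symbols, of which 215 had 0 counts in all 4 libraries. Columns were matched to samples by the short names in the labels, and groups and replicate numbers were taken from the titles. No 2 libraries agreed within sampling noise, with a chi-square of at least 17.5 per degree of freedom for each pair. Positions came from GENCODE vM21 (GRCm38), matched by symbol for 15852 symbols (96.9%). Total counts ranged from 33488569 to 35176210 per library. A floor of 3 counts per library was used for genes at 0 in a group. The floor covers counting error only. The intervals are those of odds ratios over genes taken as independent, and they do not cover the spread between libraries. No molecular identifiers were used here, so duplicate reads could not be told from separate molecules.

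The test was the edgeR 4.0.16 quasi-likelihood test, R213G against WT, with TMM normalization, the filterByExpr filter by group (13575 genes), robust estimation and Benjamini-Hochberg adjustment, with a threshold of 0.05. The design fixed beforehand asked for the defaults of edgeR version 4 and listed the legacy form as the alternative, but the installed release uses the legacy form by default, so the newer form was set explicitly. A first exploratory fit used the legacy form, and its values were seen before this was settled. Both gave 0 genes, and at an unadjusted p under 0.05 they gave 302 (newer) and 227 (legacy). The fit had 2 residual degrees of freedom, and the common dispersion was 0.14, a biological coefficient of variation of 0.374. The SE of a log2 fold change was its size divided by the square root of its F statistic. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so no such test was used for single genes. Tests were run in R 4.3.3 and Python 3.11.15 (scipy 1.17.1).

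Gene lists, 46 in all, were written before the data were examined, and 42 had at least 3 tested members and entered the set test (camera in limma 3.58.1 with a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2). The lists of sex-linked and substrain genes served as checks and were not set-tested. A list score is the mean log2 CPM of its tested members. Some members were not in the table or did not pass the filter and are not analysed here.

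The rule for named genes was also fixed beforehand: Sod3, Sod1 and Sod2; in each direction the 10 genes of largest change past the threshold with a mean of at least 5 CPM and non-overlapping libraries, or, when none passed, the 5 of smallest unadjusted p; up to 4 members of smallest p for a called list; the member of highest mean CPM for other cell type lists; at most 2 members of smallest p for other lists; and the check genes. Med28, Gm42418, Lars2 and the genes named in the closing section outside this rule were chosen after their values were seen. The values of 2 genes that the rule names are not reported here.

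The scripts were tested on simulated data: counts for the 13575 genes were drawn from the real means and library sizes, with 200 genes of a mean of at least 5 CPM changed, in 10 simulations. On average 8.5 unchanged genes were called per simulation, and a list raised by 0.5 on the log2 scale was called in 10 of 10. Each gene was drawn independently, so this does not cover lists whose members vary together, such as cell cycle (estimated correlation 0.82). Alternatives were DESeq2 size factors, upper-quartile scaling, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, the legacy form, limma voom, a replicate block, other thresholds and leaving out each library; for lists also an estimated correlation and fry; and for the region around Sod3 other windows and an unadjusted threshold.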

Results

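Recruited alveolar macrophages, the monocyte-derived macrophages that enter the airspaces after lung injury, were compared between wild-type (WT) male mice and male mice homozygous for the R213G variant of extracellular superoxide dismutase (EC-SOD), the secreted antioxidant enzyme encoded by Sod3. R213G is an arginine-to-glycine substitution in the matrix-binding region of the enzyme. The mice, 8 to 10 weeks old, had been given 100 µl of bleomycin at 1 U/ml into the trachea, a drug that injures the lung and is used to model fibrosis. The cells were sorted 7 days later as CD64 high, Siglec-F low and CD11b high, and poly(A) RNA was sequenced. There were 2 libraries per genotype, 4 in all. Total counts were 33488569 and 35176210 in R213G replicates 1 and 2 and 33573116 and 34111951 in WT replicates 1 and 2. The number of genes with at least 1 count was 13584 and 15047 in R213G and 14598 and 15194 in WT. The labels do not say whether each library came from a separate mouse, so p-values measure only the spread between these libraries. Values are mean CPM (counts per 1e6 of the library size after the filter and TMM normalization) ± SD over the 2 libraries of a genotype, and log2 fold changes are R213G minus WT ± SE.

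Sod3, on chromosome 5 from 52363791 to 52371418 (GRCm38, plus strand), was a low transcript in both genotypes. It had 4 and 47 counts in the R213G libraries and 47 and 96 in the WT libraries, or 0.734 ± 0.872 CPM against 2.11 ± 0.972 CPM. Its log2 fold change of -1.52 ± 0.93 did not pass the test (edgeR quasi-likelihood, unadjusted p = 0.135). It was -0.65 without R213G replicate 1 and -4.14 without R213G replicate 2. The cytosolic enzyme Sod1 was measured at 61.3 ± 9.89 CPM in R213G and 52.7 ± 7.50 CPM in WT (log2 fold change 0.22 ± 0.18), and the mitochondrial enzyme Sod2 at 123 ± 21.5 and 128 ± 6.80 CPM (-0.06 ± 0.15). Ccs, the copper chaperone that loads Sod1, had a log2 fold change of 0.32 ± 0.23. None of the 4 genes of this group passed.

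The first question was which genes differed between R213G and WT macrophages. No gene passed: 0 of 13575 tested genes were higher and 0 were lower in R213G at an adjusted p under 0.05 (edgeR quasi-likelihood with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 302 genes, 127 higher and 175 lower, where chance alone gives 679. That count depended on single libraries: it was 1960 without R213G replicate 2 and 71 without WT replicate 1. DESeq2 called 1 gene, Clrn2 (adjusted p = 0.0152), and limma voom called 0. The libraries of the genotypes did not overlap for 28.9% of the genes, against 33.3% by chance. Without R213G replicate 2 the log2 fold changes of Gm42418 and Lars2 were 1.3 and 1.25. Both genes were highest in R213G replicate 1 and lowest in R213G replicate 2, so these values reflect 1 library and not the genotype. In simulated data with this design, 12.0% of genes changed by 1.5-fold, 55.6% changed by 2-fold, 90.4% changed by 4-fold and 97.0% changed by 8-fold were recovered among 13575 genes. The changed genes were drawn from those with a mean of at least 5 CPM, so these shares do not cover lower genes such as Sod3. Shifts shared by many genes of a library were not simulated, so the shares may be too high for these data.

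The 5 genes of smallest p in each direction, none of which passed, are given as values. Toward R213G, Lap3, a leucine aminopeptidase induced by interferon gamma, was at 163 ± 38.9 CPM against 100.0 ± 3.83 CPM (log2 fold change 0.71 ± 0.17, unadjusted p = 0.00198). Primpol, a primase and polymerase that restarts stalled replication forks, was at 17.1 ± 0.591 against 8.18 ± 1.21 CPM, and Eme1, a subunit of a structure-specific DNA endonuclease, at 15.3 ± 0.000343 against 5.90 ± 3.81 CPM. Thg1l, which adds a guanylate to histidine tRNA, was at 12.9 ± 2.92 against 5.77 ± 0.497 CPM. Clrn2, a clarin-family membrane protein, had 35 and 181 counts in the R213G libraries and 0 in both WT libraries, which makes it at least 34.9-fold higher against a floor of 3 counts per library, or at least 11.5-fold by R213G replicate 1 alone. Toward WT, the neutrophil-attracting chemokine Cxcl2 was at 1.16 ± 0.139 CPM in R213G and 4.999 ± 0.307 CPM in WT (log2 fold change -2.10 ± 0.59, unadjusted p = 0.00555). F13a1, the A subunit of coagulation factor XIII and a monocyte and macrophage transcript, was at 140 ± 14.5 against 225 ± 70.2 CPM (log2 fold change -0.68 ± 0.19). Tmc4 was at 0.589 ± 0.833 against 4.79 ± 1.58 CPM, and the unnamed gene models 6230400D17Rik and Gm44860 were at 0.0868 ± 0.0399 against 2.08 ± 0.350 CPM and 0.103 ± 0.145 against 1.96 ± 0.0944 CPM. The log2 fold change was 2.25 instead of 1.36 for Eme1 without WT replicate 2, -2.01 instead of -3.0 for Tmc4 without R213G replicate 1, and -3.24 instead of -4.22 for Gm44860 without R213G replicate 2; Tmc4 and Gm44860 had 0 counts in the R213G library left out.

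**Figure D1:**
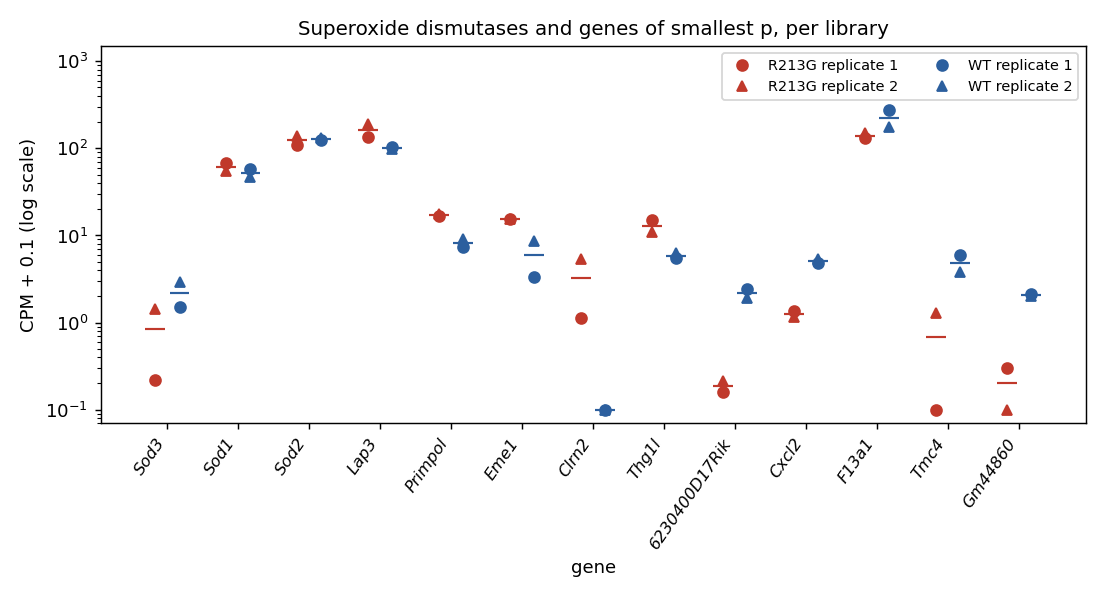
Expression of the superoxide dismutases and of the 10 genes of smallest p in each library, as CPM plus 0.1 on a log axis; red marks are R213G and blue marks WT, circles are replicate 1 and triangles replicate 2, and short lines are group means. Clrn2 had 0 counts in both WT libraries, and the Sod3 values of the 4 libraries ranged from 4 to 96 counts.

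The second question was whether gene groups fixed before the data were examined moved together. Of the 42 lists tested, 1 was called higher and 0 lower in R213G (camera, adjusted p under 0.05). The called list was cell cycle. Of its 37 members, 34 had a positive fold change, with a median of 0.291 on the log2 scale (camera adjusted p = 0.000307), but 0 members passed over all genes tested and 0 when adjusted over the list alone. The call was lost with an estimated correlation between genes (adjusted p = 0.992). That setting rests on 2 residual degrees of freedom and called 0 lists, so the loss of the adjusted call alone says little. The unadjusted camera p of the list still rose from 7.31e-06 to 0.443. The estimated correlation of its members was 0.82, against the preset of 0.01. By fry the list was not called either (adjusted p = 0.973). Members that vary together can make the preset p too small. Ccne1, which drives entry into S phase, was at 21.0 ± 5.82 CPM in R213G and 11.5 ± 3.26 CPM in WT (log2 fold change 0.86 ± 0.31). The subunits of the replicative helicase Mcm2, Mcm3 and Mcm7 had log2 fold changes of 0.47 ± 0.18, 0.37 ± 0.16 and 0.39 ± 0.18. The mean log2 CPM of the list was 5.46 and 5.76 in the R213G libraries and 4.90 and 5.70 in the WT libraries, so the gap of 0.80 between the WT libraries exceeded the difference of 0.32 between genotypes. The list was not called without WT replicate 1 (adjusted p = 0.97) or without R213G replicate 2 (adjusted p = 0.372). Airway epithelial and resident alveolar macrophage markers were also called higher without R213G replicate 1 (adjusted p = 0.0195 and 0.0111), and ribosomal protein and MHC class II genes without R213G replicate 2 (0.002 and 0.0308).

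**Figure D2:**
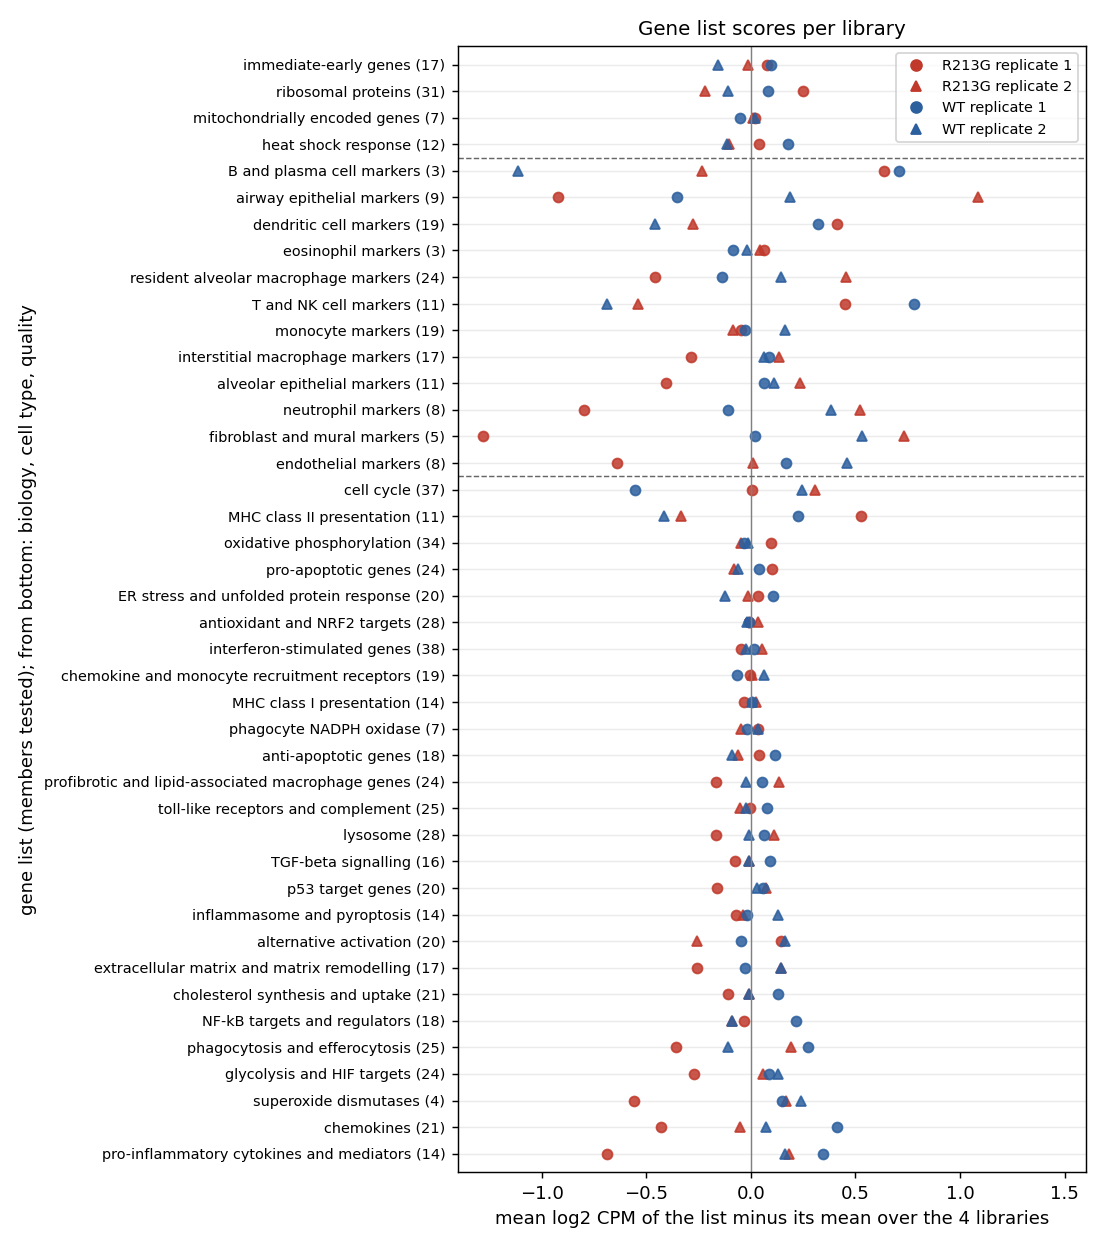
Mean log2 CPM of each gene list in each library, relative to the list's mean over the 4 libraries, with the number of tested members in parentheses; red is R213G, blue is WT, circles are replicate 1 and triangles replicate 2. The cell cycle score was lowest in WT replicate 1, at 4.90, while dendritic cell, MHC class II and T and NK cell markers separated the circles from the triangles in both genotypes.

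The title of the series names apoptosis, and 3 lists bear on it. None was called, and 0 of their members passed over all genes tested or adjusted over the list alone. Of 24 pro-apoptotic genes, 12 had a positive fold change and the median was -0.009 (camera adjusted p = 0.878). Bid, which carries death-receptor signals to mitochondria, had a log2 fold change of -0.46 ± 0.26, and Diablo, which antagonises inhibitors of caspases, 0.33 ± 0.20. Of 18 anti-apoptotic genes, 5 were positive with a median of -0.076 (adjusted p = 0.928). The Bcl2-family gene Bcl2a1d, which has near-identical paralogs, stood at 0.51 ± 0.31 and the TNF receptor adaptor Traf2 at -0.31 ± 0.22. Of 20 p53 target genes, 8 were positive with a median of -0.046 (adjusted p = 0.716), and Mdm2, the p53 ubiquitin ligase, stood at -0.26 ± 0.16 and Trp53inp1 at -0.30 ± 0.21.

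No inflammatory list was called, and 0 of their members passed over all genes tested or adjusted over the list alone. Pro-inflammatory cytokines and mediators had 4 of 14 members positive and a median log2 fold change of -0.339 (camera adjusted p = 0.611), with Il1a at -0.50 ± 0.29 and Acod1, the enzyme that makes itaconate, at -0.53 ± 0.52. The score of this list was 2.19 and 3.06 in R213G replicates 1 and 2 and 3.22 and 3.04 in WT, so R213G replicate 1 set most of the difference. NF-kB targets and regulators had 4 of 18 members positive (adjusted p = 0.611), with Nfkbiz at -0.65 ± 0.31 and the RNase Zc3h12a at -0.28 ± 0.14. Their score was 6.04 and 5.98 in R213G and 6.29 and 5.98 in WT replicates 1 and 2, so WT replicate 1 set most of that difference. Of 21 chemokines 9 were positive (adjusted p = 0.716). Beside Cxcl2, the related Cxcl3 had 0 and 8 counts in R213G and 92 and 30 in WT. Chemokine and recruitment receptors included the integrin Itga4 at -0.30 ± 0.13 and the complement receptor C5ar1 at -0.19 ± 0.15 (19 members, adjusted p = 0.928). Inflammasome genes had 4 of 14 members positive (adjusted p = 0.716), with Txnip at -0.19 ± 0.12 and Nlrp1b at -0.26 ± 0.19. Toll-like receptor and complement genes had 11 of 25 positive (adjusted p = 0.716), with C3 at -0.45 ± 0.16. Interferon-stimulated genes went both ways: 22 of 38 were positive (adjusted p = 0.716), with Oas3 at -0.50 ± 0.16 and Ifit2 at 0.31 ± 0.16.

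Neither antigen presentation list was called between genotypes. All 11 MHC class II members had a positive fold change, with a median of 0.154 (camera adjusted p = 0.716), but the scores were 9.22 and 8.36 in R213G and 8.92 and 8.28 in WT. H2-DMa stood at 0.18 ± 0.18 and H2-DMb2 at 0.60 ± 0.66. MHC class I genes had 4 of 14 positive (adjusted p = 0.978), with the immunoproteasome gene Psmb8 at 0.26 ± 0.14 and H2-T23 at -0.15 ± 0.13.

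No list of oxidant handling, stress or metabolism was called, and 0 of their members passed over all genes tested or adjusted over the list alone. Antioxidant and NRF2 target genes had 12 of 28 members positive with a median of -0.015 (camera adjusted p = 0.928), with the peroxidase Prdx6 at 0.25 ± 0.15 and the transcription factor Nfe2l2 at -0.19 ± 0.12. The phagocyte NADPH oxidase list had a median of -0.018 over 7 members (adjusted p = 0.978), with Cyba at 0.09 ± 0.11. ER stress genes had 7 of 20 positive (adjusted p = 0.928), with Chac1 at 1.21 ± 0.72 and Trib3 at -0.36 ± 0.41. Oxidative phosphorylation had 27 of 34 positive with a median of 0.09 (adjusted p = 0.611), with Cox6c at 0.45 ± 0.18 and Ndufa4 at 0.36 ± 0.23. Glycolysis and HIF targets had 12 of 24 positive (adjusted p = 0.947), with the growth factor Vegfa at -1.97 ± 0.95 and Ankrd37 at -1.82 ± 1.13, both of which had 0 counts in R213G replicate 1. Without that library the log2 fold changes were -0.99 for Vegfa and -0.84 for Ankrd37. Cholesterol synthesis and uptake had 6 of 21 positive with a median of -0.132 (adjusted p = 0.611), with Lss at -0.45 ± 0.26 and Msmo1 at -0.26 ± 0.15.

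Lists of macrophage functions tied to fibrosis and clearance were not called either, with 0 members passing over all genes tested or adjusted over the list alone. Of 24 profibrotic and lipid-associated macrophage genes, 10 were positive with a median of -0.042 (camera adjusted p = 0.978). Fn1, which encodes fibronectin, was at 10159 ± 711 CPM in R213G and 12336 ± 1552 CPM in WT (log2 fold change -0.28 ± 0.13), and the lipoprotein lipase gene Lpl at 1168 ± 66.8 and 1014 ± 197 CPM. Extracellular matrix genes had 6 of 17 positive (adjusted p = 0.716), with thrombospondin Thbs1 at -0.32 ± 0.15. TGF-beta signalling had 7 of 16 positive (adjusted p = 0.749), with Ltbp3 at -0.34 ± 0.20. Alternative activation had 13 of 20 positive with a positive median of 0.071 and a negative mean of -0.117 (adjusted p = 0.924), with Pparg at 0.40 ± 0.20 and Retnla at 52, 9, 39 and 531 counts in R213G 1, R213G 2, WT 1 and WT 2. Phagocytosis and efferocytosis genes had 10 of 25 positive (adjusted p = 0.931), with the scavenger receptor Marco at 0.92 ± 0.48 and Timd4 at -2.58 ± 1.498. Lysosome genes had 5 of 28 positive (adjusted p = 0.716), with the regulator Tfeb at 0.26 ± 0.14 and Gaa at -0.13 ± 0.11.

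Markers of other cell types were read as levels. Several markers were abundant in every library, and none of these lists was called between genotypes. The members given are the highest of each list and do not stand for the list. Mean log2 CPM over the libraries was -0.42 to 1.59 for airway epithelial, 1.4 to 2.5 for endothelial and 0.32 to 1.79 for T and NK cell markers. It was 3.73 to 4.37 for alveolar epithelial, 4.93 to 5.18 for monocyte and 6.77 to 7.19 for interstitial macrophage markers. The member of highest mean expression was Lpl for resident alveolar macrophages (24 tested, camera adjusted p = 0.611), Fn1 for monocytes (19, 0.807) and Apoe for interstitial macrophages (17, 0.716), the last at 10260 ± 175 CPM in R213G and 12175 ± 3910 CPM in WT. For granulocytes it was Mmp8 at 80.4 ± 13.7 and 99.4 ± 2.40 CPM (neutrophil list, adjusted p = 0.871) and Ear2 at 139 ± 54.6 and 116 ± 32.5 CPM (eosinophil list, 0.737). Irf8 led the dendritic list at 227 ± 9.98 and 226 ± 15.5 CPM (0.716), Il7r the T and NK list at 72.8 ± 11.3 and 84.6 ± 14.9 CPM (0.978), and Ighm the B and plasma cell list at 15.3 ± 10.97 and 11.2 ± 7.21 CPM (0.716). Among non-immune lists the leading members were Pdpn for alveolar epithelium at 370 ± 115 and 371 ± 72.7 CPM (0.978), Tppp3 for airway epithelium at 105 ± 6.30 and 103 ± 18.3 CPM (0.64), Vwf for endothelium at 113 ± 32.5 and 120 ± 13.5 CPM (0.611) and Gsn for fibroblasts and mural cells at 466 ± 46.5 and 433 ± 14.8 CPM (0.978). The mast cell and erythroid lists had 2 tested members each and no set test, with Kit at 26.0 ± 19.4 and 23.7 ± 16.0 CPM and Bpgm at 12.5 ± 2.49 and 11.6 ± 0.163 CPM. Dendritic scores were 4.63 and 3.94 in R213G and 4.54 and 3.76 in WT, so they differed within each genotype.

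None of the lists of RNA quality and handling was called between genotypes. Mitochondrially encoded genes (7 tested, camera adjusted p = 0.947) included mt-Nd6 at 0.28 ± 0.28 and mt-Nd5 at -0.06 ± 0.12, and mitochondrial transcripts took 1.64% and 1.65% of counts in R213G and 1.55% and 1.76% in WT. Heat shock genes (12, 0.978) included Hspa1a at -0.86 ± 0.51 and Hsf1 at -0.28 ± 0.18. Immediate-early genes (17, 0.716) included Dusp1 at 0.53 ± 0.24 and Zfp36 at 0.32 ± 0.20. Ribosomal protein genes (31, 0.716) included Rps23 at 0.79 ± 0.49 and Rps6 at -1.17 ± 0.75, with a positive median of 0.114. R213G replicate 1 stood apart, with the fewest genes detected and the highest Gm42418, a non-coding transcript, at 1689 CPM against 513, 671 and 702 CPM in R213G 2, WT 1 and WT 2. Lars2 was at 143 CPM there against 50.8, 62.5 and 57.2 CPM. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were expressed in all 4 libraries, and Xist had at most 31 counts, as the male labels would have it. Of the genes that differ between C57BL/6 substrains, Nnt had 0 and 2 counts in R213G and 18 and 18 in WT. Fgfbp3 had 0 and 31 against 40 and 43. Ide and Wdfy1 had log2 fold changes of 0.12 ± 0.14 and 0.03 ± 0.30. These genes do not settle whether the genotypes share a substrain, since Nnt and Fgfbp3 had few counts and R213G replicate 1 had the fewest genes detected. A difference of substrain would not be told apart from genotype in these libraries.

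The last question was whether the region around the altered gene held the differences. Of 35 tested genes within 10 Mb of Sod3, 0 passed at an adjusted p under 0.05 (edgeR), which leaves the comparison with the other 13248 genes with a position undefined. At an unadjusted p under 0.05, a threshold set before the data were examined, 3 of 35 genes passed against 291 of 13248 elsewhere (odds ratio 4.17, 95% interval 0.81 to 13.5, two-sided Fisher exact p = 0.0417). The excess did not pass with DESeq2 (odds ratio 2.21, Fisher exact p = 0.239), without R213G replicate 1 (3.74, p = 0.108) or without R213G replicate 2 (1.54, p = 0.255). It passed with voom (7.61, Fisher exact p = 0.00278), without WT replicate 1 (11.33, p = 0.0154) and without WT replicate 2 (5.62, p = 0.0196). The 3 genes were Clrn2 (45453751 to 45464149), Lap3 (45493374 to 45512691) and Med28 (45520229 to 45529276), neighbours on the plus strand of chromosome 5, the last named after its values were seen. The gaps were 29.2 kb from Clrn2 to Lap3 and 7.5 kb from Lap3 to Med28. The Fisher test counts genes as independent, so 3 neighbours measured in the same 4 libraries can make its p too small. The interval of the odds ratio in the edgeR test included 1. Med28, a subunit of the Mediator complex, was at 44.8 ± 2.65 CPM in R213G and 34.2 ± 1.77 CPM in WT. Lap3 ends 6.85 Mb before Sod3 starts, and 0 of 17 genes within 5 Mb passed.

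**Figure D3:**
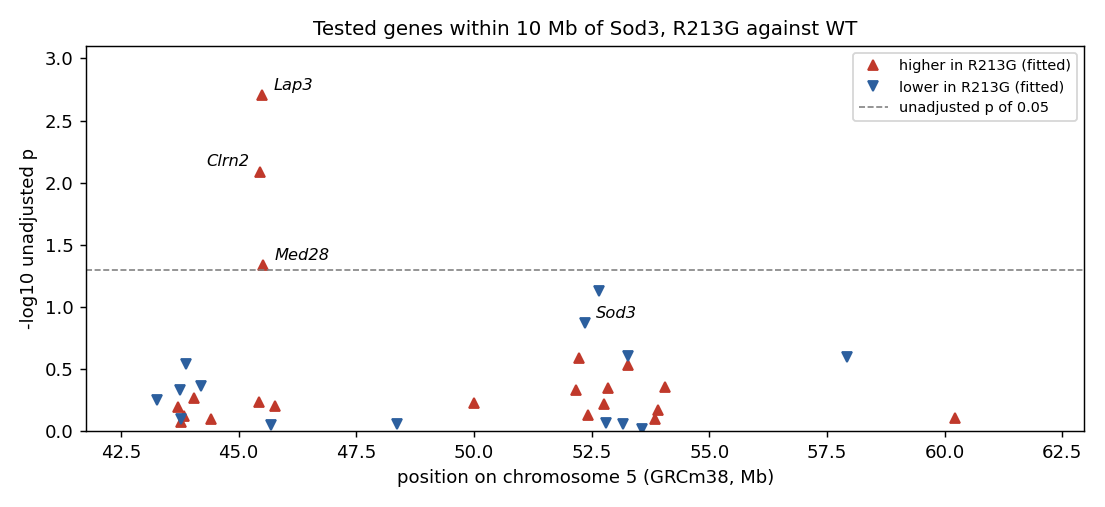
Unadjusted p (as -log10) of the 35 tested genes within 10 Mb of Sod3 along chromosome 5 in Mb (GRCm38); red upward triangles had positive and blue downward triangles negative fold changes in R213G, and the dashed line marks 0.05. Clrn2, Lap3 and Med28 lie above the line, next to each other, and Lap3 ends 6.85 Mb before Sod3 starts.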

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

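The counts near Sod3 at an unadjusted p, other than that within 10 Mb in the edgeR test, were chosen after seeing the data; all other alternatives were planned. Genes lower in R213G stayed at 0 and genes higher at 0 under every alternative except DESeq2 (1 gene, Clrn2, adjusted p 0.0152, against 0.327 to 1 elsewhere) and leave-one-out (0 to 2 genes). Lists higher numbered 1, but 0 with an estimated correlation or fry and 0 to 3 in leave-one-out fits; lists lower stayed at 0. The adjusted p of the cell cycle list was 0.992 with an estimated correlation, 0.973 with fry, and 3.01e-13 to 0.97 in leave-one-out fits, where the list's direction turned without WT replicate 1. Near Sod3, 3 genes passed at an unadjusted p within 10 Mb, 1 leaving Clrn2 and Lap3 aside, 0 leaving Med28 aside too, 0 within 5 Mb, 6 within 20 Mb (Fisher exact p = 0.143) and 22 on the chromosome (p = 0.555). Within 10 Mb other fits gave 3 genes (DESeq2 size factors, upper-quartile, no filter, legacy; Fisher exact p = 0.0203 to 0.0467), 4 (voom, Fisher exact p = 0.00278) or 2 (mean of at least 5 CPM, Fisher exact p = 0.0375; DESeq2, Fisher exact p = 0.239), and leave-one-out fits 0 (adjusted) to 8 (unadjusted, Fisher exact p = 0.255). The log2 fold change of Sod3 was -2.24 with voom and -4.14 to -0.65 in leave-one-out fits; a mean of at least 5 CPM removes Sod3, so it has no value there. With a replicate block the counts were 0 higher, 0 lower, 1 list and 2 genes near Sod3 at an unadjusted p (Fisher exact p = 0.178); deviations of same-numbered libraries correlated at 0.093 across genes, and the 2 pairs share only a number. A fit that leaves out a library assumes that the lone library varies like the other group. Of 1075 recomputed gene results, 1042 kept their sign; the 33 that did not were all leave-one-out fits of 24 genes that never passed, and the cause was not tested. Their leave-one-out ranges were: Sod2 -0.25 to 0.11, Acod1 -1.93 to 0.15, C5ar1 -0.37 to 0.01, H2-DMa -0.17 to 0.46, H2-DMb2 -0.36 to 1.42, Marco -0.08 to 1.5, Timd4 -8.82 to 1.22 (with a group at 0 counts, so not a bound), mt-Nd5 -0.18 to 0.08, Trib3 -0.77 to 0.14, Apoe -0.54 to 0.12, Ear2 -0.21 to 0.61, Ighm -0.57 to 1.31, Kit -0.94 to 1.06, Pdpn -0.37 to 0.28, Tppp3 -0.14 to 0.23, Vwf -0.4 to 0.19, Bpgm -0.1 to 0.3, Uty -0.29 to 0.06, Kdm5d -0.26 to 0.19, Ide -0.01 to 0.27, Wdfy1 -0.22 to 0.26, mt-Nd6 -0.0 to 0.62, Zfp36 -0.0 to 0.58 and Irf8 -0.06 to 0.08. Leaving out 1 library moved the fold of 16 of 91 named genes by over 1.5 times: Sod3, Acod1, H2-DMb2, Marco, Timd4, Ighm and Kit, with ranges here, Eme1, Tmc4 and Gm44860, and Cxcl3, Retnla, Vegfa, Ankrd37, Nnt and Fgfbp3.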

Other observations

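The tests of explanations given here were chosen after the patterns were seen, except the test of genes near Sod3 at an adjusted p, which was fixed beforehand; the fits of the cell cycle list without 1 library or with an estimated correlation were planned, but their use as tests of an explanation was not. The most abundant transcripts in these cells, named here after their values were seen, included genes of lysosomes and lipid handling. Lyz2, which encodes lysozyme, was at 21173 ± 2981 CPM in R213G and 23418 ± 2379 CPM in WT (SD), the sphingolipid activator Psap at 18611 ± 2420 and 19255 ± 1102 CPM, and the cathepsins Ctsd and Ctsb at 9622 ± 2824 and 9466 ± 1711 CPM in R213G and 10592 ± 1101 and 10164 ± 1101 CPM in WT.

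Splitting the 4 libraries by number called 13 genes at an adjusted p under 0.05 (edgeR), against 0 by genotype and 0 for the remaining split, which points to a structure of the samples that the labels do not name. With 3 splits no share under 0.05 can be reached. Fscn1, which bundles actin in mature dendritic cells, was at 119 and 151 CPM in R213G 1 and WT 1 and at 38.0 and 38.3 CPM in R213G 2 and WT 2 (adjusted p = 0.00831). The chemokine Ccl22 was at 147 and 166 against 60.0 and 49.6 CPM (adjusted p = 0.00831), and Itgae, the integrin CD103, at 58.7 and 36.6 against 11.8 and 6.59 CPM (adjusted p = 0.0442). The proliferation genes Mki67 and Cenpe went the other way, Mki67 at 243 and 227 against 411 and 393 CPM (adjusted p = 0.044). By camera, MHC class II (adjusted p = 4.16e-07) and dendritic cell lists (1.29e-06) were higher and the cell cycle list lower (1.2e-09) in the libraries numbered 1, and T and NK cell markers were also higher (0.0242), with Cd3e at 75 and 37 counts against 0 and 0. The other lists called by number were ribosomal proteins (5.74e-08), B and plasma cell markers (0.00871), heat shock (0.0268) and ER stress genes (0.0499), all higher in number 1, and resident alveolar macrophage (0.00871) and airway epithelial markers (0.0193), both lower. With an estimated correlation all 10 list calls were lost (adjusted p = 0.671, and 0.717 for cell cycle and ER stress). That setting rests on 2 residual degrees of freedom, and no list in any of the 3 splits had an adjusted p below 0.671 there. The loss was thus close to fixed in advance and decides nothing about these lists. The preset takes members as nearly independent, so its p can be too small for lists whose members vary together. The remaining split called 3 lists, cell cycle (0.0171), lysosome (0.00127) and profibrotic and lipid-associated macrophage genes (0.0231), all lost with an estimated correlation (0.926), against 1 for genotype, so the cell cycle list was called in each of the 3 splits.

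A candidate explanation for the dendritic genes is that dendritic-type cells were inside the CD64-high gate, which is meant to exclude most of them, in different amounts in these libraries. Of 19 list members, 10 were at least 1.5 times higher in number 1 than in number 2 in both genotypes, but this count restates how the pattern was found. The list's call is lost with an estimated correlation (adjusted p = 0.671), as all 10 list calls by number were, so that loss does not bear on the explanation. The list includes Flt3 and Zbtb46, but 7 members stand on other lists too, and of the 5 with a mean of at least 100 CPM only Ccl22 is among the 10. The libraries numbered 1 were not the deeper ones, since the higher ratio of total counts, number 1 over number 2, was 0.984. CPM values are scaled for depth in any case, so this ratio decides little. The libraries numbered 1 did have fewer genes detected, 13584 against 15047 in R213G and 14598 against 15194 in WT. Whether that trait bears on the dendritic genes was not tested. Other cells in the gate, a change of state within the macrophages and a trait of the libraries cannot be told apart. No biological explanation was tested, since the labels give no group for the numbers.

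Lap3, Clrn2 and Med28 are neighbours on chromosome 5 and lay above WT in both R213G libraries. Sequence of another strain flanking the knock-in may account for this, but neither test could decide it. In the planned test 0 genes passed an adjusted p, in the window or elsewhere. With these 3 genes left aside 0 of 32 genes in the window passed an unadjusted p (odds ratio 0, 95% interval 0 to 5.47). That count was fixed in advance, since these 3 were the only genes of the window that had passed. Strain sequence and genotype therefore cannot be told apart. Reads of Lap3 counted at Clrn2 at a constant share are argued against. Clrn2 counts were 0.76% and 2.73% of Lap3 counts in R213G replicates 1 and 2. At the lower share the WT libraries would hold 50.9 Clrn2 counts, and they hold 0. A share that differs between genotypes was not tested. The 0 counts of Clrn2 in WT were not unusual by themselves: 11 genes showed at least 35 counts in 2 libraries and 0 in the other 2 over the 5 other choices of libraries. Clrn2 was the only such gene for the 2 R213G libraries. Of the 11, Mss51 had its counts in both WT libraries, so it also followed genotype. R213G 2 with WT 2 gave 6, R213G 2 with WT 1 gave 2, and R213G 1 gave 1 with WT 1 and 1 with WT 2. An effect of the R213G genotype itself stays open and untested.

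The higher cell cycle list in R213G may rest on 1 WT library, since without WT replicate 1 its adjusted p was 0.97 and its direction turned. That library was singled out after its score was seen, and the call was also lost without R213G replicate 2, so the dependence is not on that library alone. The call was lost with an estimated correlation too (camera adjusted p = 0.992), but that setting called 0 lists. The estimated correlation of the list's members was 0.82, so the p at the preset correlation may be too small. Dilution of that library by cells low in lysosome and lipid-associated macrophage genes is argued against by those genes. Their median difference between WT replicates 1 and 2 was 0.09 on the log2 scale over 49 genes, against -0.83 for 37 cell cycle genes. The test does not cover cells that express those genes themselves, so dilution by such cells stays open. An effect of fewer detected genes cannot be told apart: R213G replicate 1, which had the fewest, scored 0.56 above WT replicate 1, but in each genotype the library with fewer genes scored lower (5.46 against 5.76 in R213G and 4.90 against 5.70 in WT). Whether fewer macrophages cycled in that sample stays open.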
